A study of Mus musculus with 8 samples.

How the data were processed

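RNA was sequenced from mouse trophoblast stem cells with intact Pr-Set7 (WT) or after doxycycline-driven loss of Pr-Set7 (KO), in 8 libraries: 2 WT and 2 KO libraries at 24 h, and 2 WT and 2 KO libraries at 48 h. Total RNA was extracted with Trizol and sequenced on an MGISEQ instrument, per the labels. Doxycycline was given to the KO cells alone. The treatment text in the labels gives 48 h for every library, whereas 4 library titles give 24 h, and the titles were followed. The series text speaks of independent experiments, but the labels do not say which libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical in part.

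The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped reads of the library), per the file headers, rounded to 2 decimals, whereas the series text speaks of RPKM. TopHat, edgeR and the mouse build mm10 are named in the submitters' processing notes, with no version or role. The gene annotation, the counting program, its strand setting and the filter on genes are not given in the sources used here. The authors deposited a table for each time, and the lowest mean FPKM over its 4 libraries was 1.25 at 24 h and 0.998 at 48 h, so genes with low values had been left out before deposit. A gene low in WT would be measured only if it was higher in KO, which favours rises in lists with few measured members. Each table also holds the authors' fold (a ratio of KO over control) and the authors' p-value for each gene, deposited with 2 decimals. That fold lay within 5% of the ratio of the group mean FPKM for 99.98% of genes at 24 h and 99.52% at 48 h. Sequencing depth is unknown from FPKM, and no interval for counting error was computed. FPKM values were too coarsely rounded to recover whole reads, so no test on counts was run.

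The 48 h table has 14754 entries. The 24 h table has 12825, of which 15 carry calendar dates in place of gene names and were left out, leaving 12810. Names were matched to RefSeq symbols of GRCm38 (12784 entries directly and 40 through older symbols at 48 h, 11246 and 54 at 24 h) and to GENCODE M21 (a further 1833 and 1439). The remaining 97 and 71 entries kept their deposited names. Coordinates are those of RefSeq where the symbol was matched there and of GENCODE M21 otherwise. Both are on GRCm38, the assembly that mm10 denotes. Strands come from GENCODE M21. After matching, 12520 genes were in both tables, 290 only in the 24 h table and 2234 only in the 48 h table. At 48 h the KO columns carry numbers that match no title, so they are known as KO libraries only, and are called KO columns 1 and 2.

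Each time was fitted on its own 4 libraries with limma 3.58.1 in R 4.3.3 (linear model on log2(FPKM + 1), empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment over all genes tested). Genes needed a mean FPKM of at least 1, which left out 0 genes at 24 h and 1 at 48 h. A gene was called at an adjusted p under 0.05. Fold changes are KO minus WT on the log2(FPKM + 1) scale, which understates the change of genes with low values. No further scaling was applied. The median gene lay at −0.03 at 24 h and −0.12 at 48 h, and log2 changes in the text are given relative to it unless called unadjusted. The tests were on unadjusted changes. The change at 48 h was compared with that at 24 h by a contrast of differences over all 8 libraries with 4 group means, which takes up any offset of a gene between the tables. The tables were made separately and the library titles follow a different scheme at each time, so time cannot be told apart from batch and FPKM levels of the 2 tables were compared in no test.

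Before the data were examined, 31 gene lists (942 genes) were fixed from textbook knowledge: stem cell, differentiation and other cell type markers of the trophoblast and its neighbours, pluripotency, germline, imprinted and long noncoding RNA genes, chromatin and histone genes, cell cycle, DNA repair, p53, cell death, interferon, stress, growth factor and metabolic genes. A list with at least 5 measured members was tested with camera (limma), which compares its members with all other genes. It was run at a preset correlation of 0.01 between genes and again with the correlation estimated from the data. The estimated version takes its degrees of freedom from the few libraries and so has little power. A list that does not pass it is therefore not shown to have failed because its genes are correlated. Calls were also counted with the adjustment over the list alone. Some lists share members, among them the interferon and nucleic acid sensing lists and the apoptosis and p53 lists. Such lists are not separate evidence. "Rose" and "fell" refer to called genes.

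Genes are named by a rule fixed in advance. It takes Kmt5a, then at each time the 12 called genes with the largest rise and the 12 with the largest fall whose KO libraries both lie beyond both WT libraries (predicted and clone names left out). It adds up to 4 members of each list with the smallest p, members given as not passing, and the 5 genes with the largest difference between times in each direction. Members named outside the rule are said to have been chosen after their values were seen.

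The fits were tested on simulated data built on the real tables. At 24 h (12676 genes) 48% of 100 genes changed by 0.5 on the log2 scale and 89% of 100 genes changed by 1 were recovered, with 5 false calls. At 48 h (14048 genes) the shares were 30% and 73%, with 5 false calls. For the difference between times (12505 genes), 84.5% of 200 genes changed by 1 were recovered, with 22 false calls. These were a larger share of the calls than an adjusted p under 0.05 aims for. A list of 40 genes lowered by 0.3 was recovered at both times and no other list was called. Few genes were changed in the simulations, whereas 29.1% of real genes were called at 24 h and 59.1% at 48 h. The rates of recovered and false calls may therefore differ in the real data. The simulated genes varied independently of each other. Real lists had estimated correlations as high as 0.969 at 24 h (fibroblast markers, 5 measured) and 0.81 at 48 h (ribosomal proteins). The G2/M and mitosis list had 0.712 at 24 h. The simulation therefore does not show how often real lists are falsely called at the preset correlation.

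Alternatives were pseudocounts of 0.1 and 0.5, a minimum mean FPKM of 5 and no minimum, equal medians, quantile normalization, a trimmed mean of log ratios to the WT mean (called TMM-like scaling), robust empirical Bayes, no mean-variance trend, a joint fit of all 8 libraries, an adjusted p under 0.1, a further minimum of 1 on the absolute log2 change, lists limited to genes in both tables, a replicate block at 24 h, and leaving out each library in turn. With a library left out, its group has 1 library, which is assumed to vary like the other group. Scaling to equal FPKM sums and 8 further gene lists were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.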

Results

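Gene expression was measured by RNA sequencing in mouse trophoblast stem cells, which are derived from the placental lineage and are kept proliferating with FGF4, heparin and TGF-β. The study compared cells with intact Pr-Set7 (WT) with cells that had lost it (KO) after doxycycline, a drug used to switch on inducible constructs. Pr-Set7, also called Set8 and encoded by Kmt5a, is the enzyme that places a single methyl group on lysine 20 of histone H4. There were 8 libraries, 2 WT and 2 KO at 24 h and 2 WT and 2 KO at 48 h. The summed FPKM was between 269649 and 280539 at 24 h and between 306800 and 353062 at 48 h. Read depth is unknown, because the values were deposited as FPKM. A single noncoding entry held 18.0% to 21.2% of the sum at 24 h (Gm26917) and 22.2% to 27.0% at 48 h (CT010467.2). Libraries of the same group were more alike than libraries of different groups at both times. The Pearson correlation across genes, which are not independent replicates, was 0.992 within both groups against at most 0.971 between them at 24 h. At 48 h it was at least 0.988 within groups and at most 0.914 between them.

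The transcript of the targeted gene was lower in every KO library than in either WT library. Kmt5a (protein coding, chromosome 5, 124439930 to 124462311, plus strand, GRCm38) was at 21.7 and 20.8 FPKM in the WT libraries and 17.48 and 17.3 FPKM in the KO libraries at 24 h. At 48 h it was at 39.18 and 38.44 FPKM in WT and at 30.95 and 32.89 FPKM in KO. The KO mean was 81.8% of the WT mean at 24 h and 82.2% at 48 h. The unadjusted log2 change was −0.28 at both times (SE 0.046, adjusted p = 0.0153 at 24 h; SE 0.05, adjusted p = 0.00818 at 48 h, limma). Relative to the median gene it was −0.24 and −0.15. The authors' deposited p-value for Kmt5a, from a test that is not described, was 0.2 at 24 h and 0.47 at 48 h. The part of the gene that was deleted is not given in the sources used here, so a value for the whole gene does not check the deletion. The call at 24 h was lost without any 1 of the libraries, at adjusted p = 0.085 without WT library 1, 0.0623 without WT library 2, 0.071 without KO library 1 and 0.0651 without KO library 2. At 48 h it was lost with TMM-like scaling (adjusted p = 0.0671), equal FPKM sums (0.139) and without KO column 1 (0.0561).

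**Figure D1:**
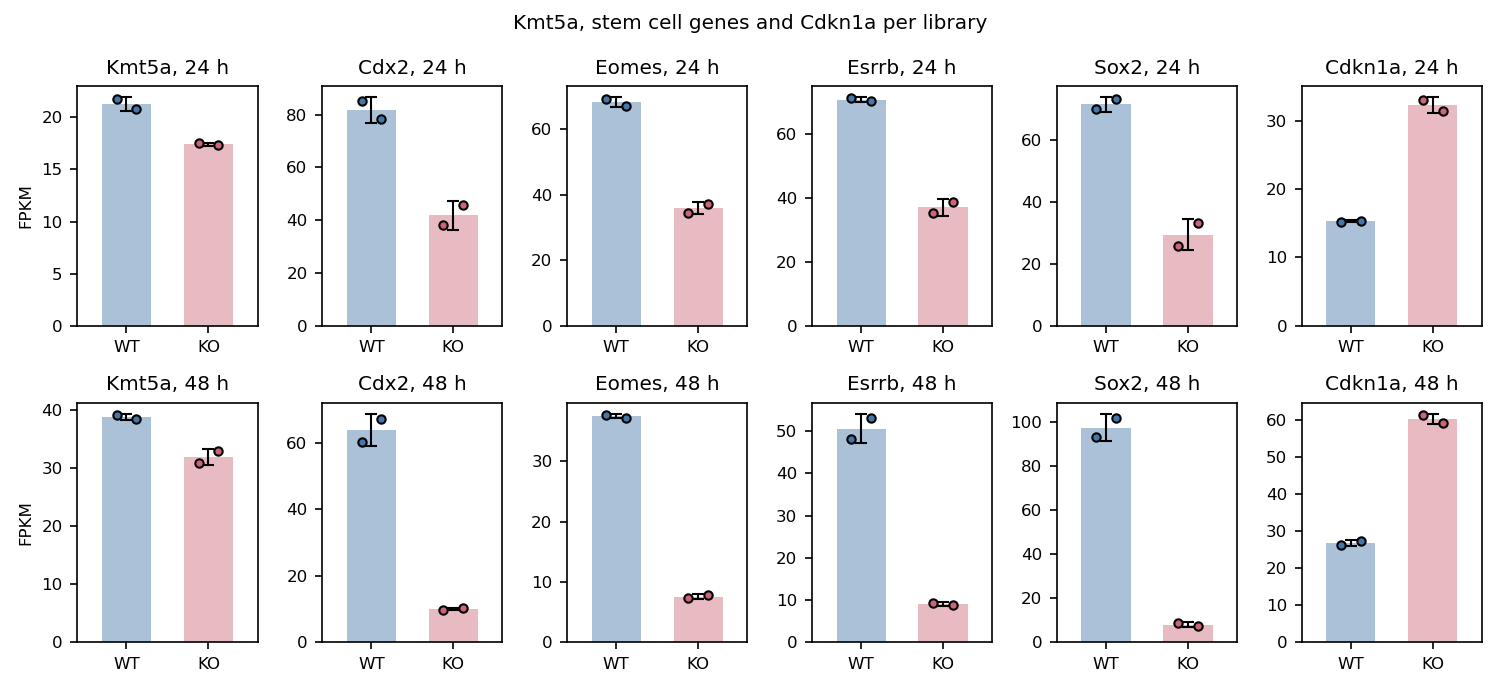
FPKM of Kmt5a, 4 stem cell genes (Cdx2, Eomes, Esrrb, Sox2) and Cdkn1a in WT and KO cells at 24 h (upper panels) and 48 h (lower panels). Bars are means of 2 libraries, error bars are SD and points are libraries. Kmt5a fell to 82.2% of WT at 48 h while Sox2 went from 97.3 to 8.06 FPKM. The panels have separate axes, and levels at the 2 times come from separately made tables.

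The first comparison asked which transcripts had changed 24 h after doxycycline. Of 28 measured trophoblast stem cell markers 20 fell and 1 rose, of 49 replication-dependent histone genes 47 fell and 0 rose, and of 30 p53 targets 22 rose and 0 fell. These 3 lists passed camera at the preset correlation and did not with an estimated correlation (adjusted p = 0.474, 0.495 and 0.474). Eomes, a transcription factor needed for trophoblast stem cells, fell from 68.2 ± 1.44 to 35.8 ± 1.86 FPKM (mean ± SD, n = 2). Nr0b1, an orphan nuclear receptor, had the largest fall of all named genes, from 10.7 ± 2.37 to 1.17 ± 0.248 FPKM (log2 change −2.39, adjusted p = 0.00228). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 15.3 ± 0.099 to 32.2 ± 1.16 FPKM (log2 change 1.06, adjusted p = 0.00143). Of 12810 genes tested, 1743 rose and 1982 fell. The share of calls that were lower was 53.2%, against 44.9% with TMM-like scaling (1988 higher and 1618 lower), 58.7% with equal medians (1631 and 2316), 50.2% with quantile normalization (1791 and 1806) and 55.5% with equal FPKM sums, a scaling chosen after seeing the data (1593 and 1987). The number of calls was lower with any 1 library left out, where a group has 1 library and the test has less power. From 3725 with all libraries it went to 1256 without WT library 1, 1224 without WT library 2, 1354 without KO library 1 and 2170 without KO library 2. Among the calls 198 rises and 61 falls had an unadjusted log2 change of at least 1 in size. The authors' deposited table has 1203 genes with p under 0.05 at 24 h, where limma had 5527 at an unadjusted p under 0.05. Whether the authors' p-value is adjusted is not given.

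The largest rise at 24 h was that of the adhesion G protein-coupled receptor gene Adgrg1, from 1.03 ± 0.177 to 12.8 ± 2.77 FPKM (log2 change 2.79, adjusted p = 0.00184). Plau, which encodes urokinase plasminogen activator, rose from 3.82 ± 1.24 to 22.5 ± 4.43 FPKM. The Wnt ligand gene Wnt9a rose by 2.19 on the log2 scale, Gna15, a G protein subunit, by 2.15, and the receptor tyrosine kinase gene Axl by 1.98. Inka1, Sec14l5, Mab21l3, Neurl2, Creb3l1, Zfp365 and Hyal1, the last encoding a lysosomal hyaluronidase, rose by between 1.86 and 2.35. Among the falls, the imprinted gene Peg10, which the placenta needs, went from 254.7 ± 2.52 to 93.8 ± 14.2 FPKM (log2 change −1.41, adjusted p = 0.00255). Upp1, encoding uridine phosphorylase, had a log2 change of −1.59, Cyp26a1, which breaks down retinoic acid, of −1.57, the transcription factor gene Zic2 of −1.45 and the growth factor receptor gene Fgfr4 of −1.34. Gdf6, Ube2ql1, Il5ra and Inpp1 fell with log2 changes between −1.41 and −1.39. Tmem181c-ps (−2.12) and the histone gene H2ac15 (−1.33) also fell. Both have near-identical copies elsewhere in the genome, so their own values are uncertain.

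Of 28 measured trophoblast stem cell markers, 20 fell and 1 rose at 24 h (22 and 2 adjusted over the list alone), with a median log2 change of −0.58 (camera adjusted p = 1.49e-07; adjusted p = 0.474 with an estimated correlation). Esrrb fell from 70.8 ± 0.665 to 37.1 ± 2.56 FPKM, and Spry4, a feedback inhibitor of FGF signalling, from 34.5 ± 2.11 to 17.8 ± 1.14 FPKM. Cdx2 (81.6 ± 4.89 to 41.9 ± 5.49 FPKM) and Sox2 (71.3 ± 2.28 to 29.4 ± 5.08 FPKM), which the rule names at 48 h, fell as well. The member that rose was Sox15 (4.97 to 9.61 FPKM), singled out after its values were seen. Of the stem cell markers, Cdx2, Eomes, Esrrb, Bmp4 and Spry4 are also on the list of FGF and ERK feedback targets. The lists are therefore not separate evidence. Of 23 FGF and ERK feedback targets, 13 fell and 1 rose (14 and 3 adjusted over the list alone; median −0.36, adjusted p = 0.00166; adjusted p = 0.474 with an estimated correlation), Spry1 from 10.4 ± 0.368 to 4.59 ± 0.0919 FPKM. Of 12 pluripotency markers, 7 fell and 2 rose, with equal counts adjusted over the list alone (adjusted p = 0.0465; adjusted p = 0.579 with an estimated correlation). The pluripotency call was lost without WT library 1 (adjusted p = 0.0631), with equal medians (0.0678), quantile normalization (0.0501) and no mean-variance trend (0.0609). Nodal, a TGF-β family ligand, rose by 0.72 on the log2 scale. Without WT library 1, WT library 2, KO library 1 and KO library 2 in turn, 15, 13, 17 and 20 stem cell markers fell, 10, 10, 11 and 13 FGF and ERK feedback targets and 1, 2, 2 and 6 pluripotency markers.

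All 49 measured replication-dependent histone genes had lower values at 24 h and 47 of them fell (49 adjusted over the list alone), with a median log2 change of −0.79 (adjusted p = 2.94e-17; adjusted p = 0.495 with an estimated correlation). H2ac4 went from 223.9 ± 16.3 to 120.9 ± 1.32 FPKM. These genes share near-identical sequence, so the division of reads among them is uncertain, but their summed FPKM also went from 5330 ± 432 to 2989 ± 261. Of 40 genes of G2/M and mitosis, 25 fell and 0 rose (29 and 2 adjusted over the list alone; median −0.27, adjusted p = 5.39e-07; adjusted p = 0.596 with an estimated correlation). Ckap2l, a spindle protein gene, fell from 19.3 ± 1.1 to 13.8 ± 0.29 FPKM. Of 47 S phase genes, 20 fell and 2 rose (22 and 4 adjusted over the list alone; median −0.15, adjusted p = 0.00998; adjusted p = 0.551 with an estimated correlation), among them the DNA ligase gene Lig1 (33.6 ± 0.693 to 24.6 ± 0.41 FPKM). Of 38 DNA repair genes, 12 fell and 7 rose (17 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.0716; 0.596 with an estimated correlation). H2ax fell from 222.8 ± 2.16 to 152.4 ± 1.97 FPKM and Xrcc1 rose from 7.5 ± 0.24 to 10.8 ± 0.269 FPKM. Without WT library 1, WT library 2, KO library 1 and KO library 2 in turn, 34, 43, 33 and 38 histone genes fell, 3, 1, 7 and 20 genes of G2/M and mitosis, 4, 2, 4 and 10 S phase genes and 4, 3, 4 and 6 DNA repair genes, with 1, 2, 2 and 2 DNA repair genes that rose.

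Of 30 measured p53 targets, 22 rose and 0 fell at 24 h (25 and 0 adjusted over the list alone), with a median log2 change of 0.55 (adjusted p = 1e-12; adjusted p = 0.474 with an estimated correlation). Pidd1, which encodes a death domain protein, rose from 6.59 ± 0.219 to 17.8 ± 0.636 FPKM, Ddit4l by 1.12 and Ei24 by 0.89 on the log2 scale. Of 21 apoptosis genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone; adjusted p = 0.0216; adjusted p = 0.474 with an estimated correlation). Pmaip1, encoding the pro-apoptotic protein Noxa and also a p53 target, rose from 15.6 ± 1.97 to 31.5 ± 0.559 FPKM. Of 12 necroptosis and pyroptosis genes, 4 rose and 0 fell, in the same numbers adjusted over the list alone (adjusted p = 0.00995; adjusted p = 0.474 with an estimated correlation). Mlkl, the pore-forming effector of necroptosis, rose from 3.07 ± 0.198 to 5.89 ± 0.226 FPKM. Of 20 macrophage and leukocyte markers 5 were measured. Among them 3 rose and 0 fell, likewise adjusted over the list alone (adjusted p = 0.02, and 0.474 with an estimated correlation), Cd68 from 2.38 ± 0.24 to 4.88 ± 0.156 FPKM. Without WT library 1, WT library 2, KO library 1 and KO library 2 in turn, 17, 19, 17 and 18 p53 targets rose, 4, 5, 4 and 5 apoptosis genes, 4, 1, 2 and 3 necroptosis and pyroptosis genes and 2 macrophage and leukocyte markers each time. The mitochondrial share of the FPKM sum was 2.24% and 2.35% in WT and 2.3% in both KO libraries.

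Of 23 cholesterol synthesis genes, 13 fell and 0 rose at 24 h (15 and 1 adjusted over the list alone, 6 and 0 with quantile normalization; median −0.17, adjusted p = 0.000318; adjusted p = 0.596 with an estimated correlation). Cyp51 went from 62.7 ± 3.76 to 44.1 ± 2.11 FPKM. Of 35 heterochromatin and retroelement silencing genes, 17 fell and 2 rose (21 and 2 adjusted over the list alone; median −0.17, adjusted p = 0.000172; adjusted p = 0.474 with an estimated correlation). Trim28, a corepressor of retroelements, fell from 166.4 ± 0.156 to 124.0 ± 0.141 FPKM, while Zfp809, which recruits it to retroviral DNA, rose by 0.62 on the log2 scale. Of 21 genes for H4K20 methylation and linked chromatin readers, a list that includes Kmt5a, 6 fell and 2 rose (11 and 3 adjusted over the list alone, 10 and 2 with equal medians; adjusted p = 0.02; adjusted p = 0.474 with an estimated correlation). That call was lost with a minimum mean FPKM of 5 (adjusted p = 0.0734). Of the named members, Kmt5c, an enzyme that adds further methyl groups at this residue, was at 7.31 ± 0.304 FPKM in WT and 10.2 ± 0.141 FPKM in KO (adjusted p = 0.00803, and 0.0511 without WT library 1). Without WT library 1, WT library 2, KO library 1 and KO library 2 in turn, 3, 5, 4 and 5 cholesterol synthesis genes fell, 8, 2, 7 and 11 heterochromatin and retroelement silencing genes and 1, 1, 1 and 2 genes of the H4K20 list.

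The other lists did not pass at 24 h. Of 25 imprinted genes, 11 fell and 3 rose (13 and 5 adjusted over the list alone; adjusted p = 0.069), with Mest at 59.5 ± 0.53 FPKM in WT and 24.8 ± 0.396 FPKM in KO (adjusted p = 0.00133). NF-kB targets had 1 rise and 1 fall among 13 (4 and 1 adjusted over the list alone; adjusted p = 0.0522). Interferon-stimulated genes had 2 rises, Tap1 and Ifi35, and 1 fall among 16, and nucleic acid sensing genes had 1 rise (Myd88) and 1 fall among 15. The fall was the same gene, Ifih1, which is on both lists. Unfolded protein and integrated stress response genes had 6 rises and 1 fall among 26. Among trophoblast giant cell markers, 2 of 6 rose (Plau and Ppard). Spongiotrophoblast and glycogen cell markers had 1 rise and 3 falls among 9 (1 and 4 adjusted over the list alone), syncytiotrophoblast and labyrinth markers 2 and 5 among 15, endoderm markers 1 and 3 among 9, and fibroblast markers 1 and 0 among 5. Immediate early and heat shock genes had 7 rises and 5 falls among 25 (9 and 5 adjusted over the list alone), Btg2 among the rises, and glycolysis and hypoxia genes 3 and 6 among 28 (3 and 7). Oxidative phosphorylation genes had 5 rises and 2 falls among 44 (0 and 0 adjusted over the list alone, 7 and 0 with TMM-like scaling, 8 and 0 with quantile normalization). Named long noncoding RNAs had 0 rises and 4 falls among 26 (0 and 2). In limma, 0 of 52 ribosomal protein genes passed, and 0 had an unadjusted p under 0.05, while 4 rose with quantile normalization. Endoderm markers had a median of 0.09, a mean of −0.02 and a test that pointed down. Without any 1 of the libraries all 7 calls of oxidative phosphorylation genes were lost, and all 4 of the noncoding RNAs without WT library 2 and without KO library 1. Without WT library 1, WT library 2, KO library 1 and KO library 2 in turn, 6, 4, 7 and 10 imprinted genes fell, 4, 3, 5 and 6 immediate early and heat shock genes rose, 4, 5, 4 and 5 stress response genes rose, 1, 2, 1 and 4 glycolysis and hypoxia genes fell, and 2, 3, 3 and 4 syncytiotrophoblast and labyrinth markers fell. Of the spongiotrophoblast and glycogen cell markers 1 fell each time. Without KO library 2, 5 NF-kB targets rose. The 1 fall of the NF-kB, interferon-stimulated and nucleic acid sensing lists and the 1 rise of the fibroblast and endoderm lists were each lost without any 1 of the libraries. All falls of the endoderm list and both calls of the endothelial list were lost without either WT library. Where no second pair of counts is given, the counts adjusted over the list alone were equal. Of 16 endothelial markers 4 were measured, too few for a test, with 1 rise and 1 fall, and of 31 germline and 2-cell-stage genes 0 were in the table. With an estimated correlation, 0 of the 13 lists called at 24 h passed camera, and of all lists 0 had an unadjusted p under 0.05. Calls were also lost for lists whose estimated correlation lay below the preset 0.01 (apoptosis −0.022, H4K20 list 0.005). Other called lists had estimates far above the preset (G2/M and mitosis 0.712, replication-dependent histones 0.529, cholesterol synthesis 0.501). If these estimates are right, the p-values of those lists at the preset correlation are too small. With so few libraries the version with an estimated correlation has little power, so it does not decide whether the calls hold.

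The second comparison asked the same 48 h after doxycycline. Of 28 measured trophoblast stem cell markers 22 fell and 4 rose, and of 49 replication-dependent histone genes 48 fell and 0 rose. Both lists passed camera at the preset correlation and did not with an estimated correlation (adjusted p = 0.351 for each). Sox2 fell from 97.3 ± 6.21 to 8.06 ± 1.04 FPKM (mean ± SD, n = 2; log2 change −3.32, adjusted p = 0.000125), and Cdx2, which specifies the trophoblast lineage, from 63.8 ± 4.87 to 10.04 ± 0.375 FPKM (log2 change −2.43, adjusted p = 0.000125). The alpha globin gene Hba-a1 rose from 3.66 ± 1.05 to 62.7 ± 7.59 FPKM (log2 change 3.91, adjusted p = 0.000223). Evpl, encoding envoplakin of the cornified envelope, rose from 1.13 ± 0.0919 to 22.5 ± 0.488 FPKM (log2 change 3.59, adjusted p = 0.000122). Of 14753 genes tested, 3367 rose and 5352 fell, 59.1% of all genes. The share of calls that were lower was 61.4%, against 48.4% with TMM-like scaling (4341 higher and 4077 lower), 53.8% with equal medians (3923 and 4573), 53.6% with quantile normalization (3967 and 4589) and 49.5% with equal FPKM sums, a scaling chosen after seeing the data (3812 and 3730). Of the calls, 840 rises and 625 falls had an unadjusted log2 change of at least 1 in size. The authors' deposited table has 1608 genes with p under 0.05 at 48 h, where limma had 9466 at an unadjusted p under 0.05.

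Further large rises at 48 h were Ndufa4l2, a hypoxia-responsive mitochondrial gene (1.63 ± 0.269 to 30.5 ± 1.76 FPKM), Slc39a4, encoding a zinc importer (2.69 ± 0.0424 to 30.6 ± 1.252 FPKM), the extracellular matrix gene Ecm1 (5.05 ± 1.05 to 45.7 ± 0.842 FPKM) and the T-box factor gene Tbx2 (1.61 ± 0.311 to 19.3 ± 0.446 FPKM). Adgrg1 rose from 2.85 ± 0.0566 to 28.1 ± 1.32 FPKM, and Ankrd35, Atg9b, Cited4, Sytl1 and Pla1a by between 2.97 and 3.29 on the log2 scale. Besides Sox2, the largest falls were Nr0b1 (17.9 ± 0.863 to 1.65 ± 0.0424 FPKM), the transcription cofactor gene Cited1 (41.8 ± 2.19 to 5.17 ± 0.898 FPKM) and 9 histone genes. The linker histone gene H1f1 went from 300.8 ± 4.08 to 37.5 ± 2.91 FPKM and the core histone gene H4c12 from 131.3 ± 4.89 to 13.9 ± 0.46 FPKM. H2bc12, H2ac15, H2bc15, H2ac8, H2ac12, H2ac13 and H1f5 had log2 changes between −3.04 and −2.68.

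Of 49 measured replication-dependent histone genes, 48 fell and 0 rose at 48 h, with the same numbers adjusted over the list alone, and the median log2 change was −2.31 (adjusted p = 6.33e-17; adjusted p = 0.351 with an estimated correlation). Their summed FPKM, which does not depend on how reads were divided among near-identical genes, went from 7916 ± 559 to 1423 ± 0.552. Of 47 S phase genes, 41 fell and 1 rose, also adjusted over the list alone (median −0.47, adjusted p = 1.21e-07; adjusted p = 0.351 with an estimated correlation). Lig1 went from 45.8 ± 0.262 to 16.6 ± 0.559 FPKM and the replicative helicase gene Mcm6 from 51.4 ± 0.368 to 21.9 ± 0.361 FPKM. Of 40 genes of G2/M and mitosis, 38 fell and 0 rose, also adjusted over the list alone (median −0.62, adjusted p = 1.78e-09; adjusted p = 0.351 with an estimated correlation), the kinetochore gene Cenpf from 14.2 ± 0.651 to 4.97 ± 0.163 FPKM. Of 38 DNA repair genes, 30 fell and 2 rose (31 and 2 adjusted over the list alone; median −0.41, adjusted p = 4.27e-05; adjusted p = 0.351 with an estimated correlation). Bard1, the partner of Brca1, had a log2 change of −1.37, and H2ax went from 373.1 ± 21.9 to 149.1 ± 3.64 FPKM.

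Of 28 trophoblast stem cell markers, 22 fell and 4 rose at 48 h (22 and 6 adjusted over the list alone, 21 and 6 with TMM-like scaling; median −0.96, adjusted p = 0.000256; adjusted p = 0.351 with an estimated correlation). Eomes fell from 37.5 ± 0.375 to 7.58 ± 0.389 FPKM, Esrrb from 50.6 ± 3.47 to 9.13 ± 0.396 FPKM and Ddah1 from 99.3 ± 0.113 to 17.4 ± 0.827 FPKM. The 4 that rose, singled out after their values were seen, were Sox15 (4.6 ± 0.389 to 30.7 ± 2.34 FPKM), Rhox9, Ets2 and Duox2. Among markers of differentiated trophoblast, 5 of 8 giant cell genes rose and 1 fell, likewise adjusted over the list alone (median 0.84, adjusted p = 0.0224; adjusted p = 0.351 with an estimated correlation; 0.0643 with a minimum mean FPKM of 5). Of 26 giant cell markers on the list, only these 8 were measured. Plau rose from 1.08 ± 0.332 to 13.04 ± 0.516 FPKM and Mmp9, a matrix metalloproteinase gene, from 30.2 ± 0.191 to 52.1 ± 0.849 FPKM. The member that fell was Hand1 (266.1 to 194.0 FPKM, named after its values were seen). Spongiotrophoblast and glycogen cell markers had 3 rises and 3 falls among 8 (median 0.14, mean −0.11, with a test that pointed up; adjusted p = 0.787) and syncytiotrophoblast and labyrinth markers 9 and 8 among 19 (adjusted p = 0.467), with equal counts adjusted over the list alone. Pluripotency markers had 6 rises and 5 falls among 12, also adjusted over the list alone (adjusted p = 0.549). Their median was 0.37, their mean −0.08 and their test pointed up, with Lin28a, an RNA-binding protein gene of early cells, going from 88.7 ± 2.09 to 13.9 ± 0.41 FPKM.

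Markers of other cell types also moved at 48 h, among those that were measured. These were 5 of 20 macrophage and leukocyte markers, 8 of 24 fibroblast markers and 11 of 23 endoderm markers. Genes with low values had been left out before deposit, so a marker low in WT would be measured only if it was higher in KO. That favours rises in these lists. All 5 measured macrophage and leukocyte markers rose, also adjusted over the list alone (median 1.13, adjusted p = 0.00303; adjusted p = 0.351 with an estimated correlation). The lysosomal glycoprotein gene Cd68 rose from 5.22 ± 0.361 to 33.6 ± 3.83 FPKM and Csf1r from 1.26 ± 0.184 to 4.75 ± 0.339 FPKM, while Cd14 (1.24 ± 0.219 and 2.48 ± 0.29 FPKM) lost its call without KO column 1 (adjusted p = 0.0675). Of 8 fibroblast markers, 6 rose and 0 fell, also adjusted over the list alone (median 1.06, adjusted p = 0.00058; adjusted p = 0.351 with an estimated correlation), the collagen gene Col6a1 from 0.795 ± 0.0212 to 6.44 ± 0.248 FPKM and the fibronectin gene Fn1 from 2.94 ± 0.184 to 10.9 ± 0.149 FPKM. Of 11 endoderm markers, 7 rose and 3 fell, also adjusted over the list alone (median 0.59, adjusted p = 0.0341; adjusted p = 0.351 with an estimated correlation). The basement membrane genes Col4a1 (28.0 ± 0.658 to 78.9 ± 0.134 FPKM), Col4a2 and Sparc were among the rises. Without KO column 1 the macrophage list had 3 rises. The endoderm call was lost without WT library 2 (adjusted p = 0.053), without KO column 2 (0.0687), with TMM-like scaling (0.0592), equal FPKM sums (0.0699) and a minimum mean FPKM of 5 (0.0873). Endothelial markers had 3 rises and 1 fall among 6 (3 and 2 adjusted over the list alone, 1 and 1 without KO column 1, 1 and 2 without KO column 2; adjusted p = 0.215), and of 2 measured germline and 2-cell-stage genes Piwil2 was at 1.13 ± 0.0919 FPKM in WT and 1.69 ± 0.177 FPKM in KO (adjusted p = 0.0496, and 0.0996, 0.213, 0.138 and 0.0827 without KO column 1, KO column 2, WT library 1 and WT library 2). The other, Taf7l, did not pass (adjusted p = 0.0654), and both passed adjusted over the list alone. The mitochondrial share of the FPKM sum was 1.36% and 1.14% in WT and 1.71% and 1.83% in KO.

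Of 34 p53 targets, 18 rose and 5 fell at 48 h, also adjusted over the list alone (20 and 3 with TMM-like scaling; median 0.42, adjusted p = 0.00173; adjusted p = 0.351 with an estimated correlation). Cdkn1a rose from 26.7 ± 0.806 to 60.2 ± 1.4 FPKM and the death receptor gene Fas from 0.66 ± 0.17 to 4.46 ± 0.184 FPKM. The members that fell, named after their values were seen, were Sulf2, Gtse1, Bbc3, Sesn1 and Zmat3, with log2 changes between −0.33 and −0.08, of which Bbc3 (adjusted p = 0.163) and Zmat3 (0.349) did not pass with TMM-like scaling. Without KO column 1 and KO column 2 there were 2 and 3 falls. Mdm2, the gene of the main p53 ubiquitin ligase, was at 105.7 ± 3.66 FPKM in WT and 106.9 ± 0.834 FPKM in KO (adjusted p = 0.795). Of 13 necroptosis and pyroptosis genes, 8 rose and 0 fell, also adjusted over the list alone (median 0.63, adjusted p = 0.000854; adjusted p = 0.351 with an estimated correlation), with 5 rises without KO column 1 and 5 without KO column 2. The necroptosis and pyroptosis list holds 20 genes. Those low in WT would be measured only if higher in KO, which favours rises. Mlkl rose from 0.71 ± 0.141 to 5.98 ± 0.29 FPKM, the receptor gene Tnfrsf1a from 1.86 ± 0.24 to 8.18 ± 0.566 FPKM and Gsdmd, the pore-forming effector of pyroptosis, from 6.91 ± 0.29 to 15.5 ± 0.629 FPKM. Apoptosis genes had 9 rises and 7 falls among 22 (10 and 7 adjusted over the list alone, 12 and 4 with TMM-like scaling, 8 and 3 without KO column 1, 8 and 4 without KO column 2) and did not pass (adjusted p = 0.0528).

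Only 27 of 50 interferon-stimulated, 17 of 30 nucleic acid sensing and 13 of 30 NF-kB genes were measured at 48 h. Genes low in WT would be measured only if higher in KO, which favours rises in these lists too. Of 27 interferon-stimulated genes, 11 rose and 6 fell, also adjusted over the list alone (median 0.29, adjusted p = 0.0111; adjusted p = 0.351 with an estimated correlation; 0.116 with a minimum mean FPKM of 5). Isg20, an exonuclease gene, rose from 2.29 ± 0.0212 to 7.8 ± 0.0778 FPKM, whereas Dtx3l, named after its values were seen, was the member with the largest fall. With TMM-like scaling 13 interferon-stimulated genes rose and 3 fell, and without WT library 1, WT library 2 and KO column 1 the falls were 3, 3 and 1, while all were lost without KO column 2. Of 17 nucleic acid sensing genes, 6 rose and 3 fell, also adjusted over the list alone (9 and 1 with TMM-like scaling, 8 and 1 with equal medians and with quantile normalization, 5 and 1 without any 1 of the libraries; adjusted p = 0.0384; adjusted p = 0.351 with an estimated correlation). The kinase gene Ikbke rose from 0.355 ± 0.0778 to 6.63 ± 0.0141 FPKM, and the nucleotide phosphohydrolase gene Samhd1 fell from 7.82 ± 0.0495 to 3.99 ± 0.262 FPKM. The call was lost without WT library 2 (adjusted p = 0.0664), without KO column 2 (0.055) and with a minimum mean FPKM of 5 (0.192). Of 13 NF-kB targets, 8 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0343; adjusted p = 0.351 with an estimated correlation), the chemokine gene Cxcl16 from 5.31 ± 0.0283 to 14.4 ± 0.156 FPKM. Without KO column 2 there were 5 rises and 1 fall. Here the call was lost without WT library 2 (adjusted p = 0.0573), with TMM-like scaling (0.0502), equal FPKM sums (0.0539) and a minimum mean FPKM of 5 (0.128). Of 25 immediate early and heat shock genes, 15 rose and 4 fell (17 and 4 adjusted over the list alone; median 0.5, adjusted p = 0.00129; adjusted p = 0.351 with an estimated correlation). The small heat shock protein gene Hspb1 rose from 114.3 ± 4.7 to 397.7 ± 2.24 FPKM. Unfolded protein and integrated stress response genes had 12 rises and 6 falls among 27, also adjusted over the list alone (7 and 5 without KO column 1 and without KO column 2; adjusted p = 0.0942), with the chaperone gene Calr higher and the amino acid synthesis genes Asns and Psat1 lower.

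Of 23 cholesterol synthesis genes, 22 fell and 0 rose at 48 h (23 and 0 adjusted over the list alone; median −0.83, adjusted p = 4.74e-07; adjusted p = 0.351 with an estimated correlation). Insig1, a sterol sensor gene, went from 64.8 ± 0.248 to 18.8 ± 0.12 FPKM and Mvd from 88.3 ± 3.39 to 24.9 ± 1.22 FPKM. Of 30 glycolysis and hypoxia genes, 22 fell and 5 rose, also adjusted over the list alone (adjusted p = 0.0107; adjusted p = 0.353 with an estimated correlation), with the enolase gene Eno1 going from 277.2 ± 4.99 to 130.7 ± 3.76 FPKM. Of 35 heterochromatin and retroelement silencing genes, 24 fell and 6 rose, also adjusted over the list alone (23 and 3 without KO column 1, 23 and 1 without KO column 2; median −0.46, adjusted p = 0.00375; adjusted p = 0.461 with an estimated correlation). The DNA methyltransferase gene Dnmt3b went from 95.9 ± 0.488 to 36.2 ± 1.68 FPKM. Of 22 genes for H4K20 methylation and linked chromatin readers, 16 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0228; adjusted p = 0.351 with an estimated correlation), with the condensin II genes Ncapg2 (8.1 ± 0.396 to 3.08 ± 0.0283 FPKM) and Ncapd3 at the smallest p. Of 29 named long noncoding RNAs, 17 fell and 3 rose (18 and 3 adjusted over the list alone; adjusted p = 0.0386; adjusted p = 0.45 with an estimated correlation), Snhg6 from 13.2 ± 0.127 to 6.54 ± 0.0141 FPKM. The noncoding RNA call was lost without WT library 1 (adjusted p = 0.0758), without KO column 2 (0.0562) and with a minimum mean FPKM of 5 (0.0873).

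Of 52 ribosomal protein genes, 23 fell and 0 rose at 48 h (22 and 0 adjusted over the list alone; median −0.12, adjusted p = 0.00786; adjusted p = 0.784 with an estimated correlation), but the median turned to 0.02 with quantile normalization, where 12 fell and 5 rose, and 12 fell and 0 rose with TMM-like scaling. Without WT library 1, WT library 2, KO column 1 and KO column 2 in turn, 27, 15, 4 and 10 fell. That call was also lost with TMM-like scaling (adjusted p = 0.0649), without KO column 1 (0.0554) and without WT library 2 (0.0883). Oxidative phosphorylation genes had 12 rises and 16 falls among 44 (12 and 17 adjusted over the list alone, 17 and 13 with TMM-like scaling, 14 and 14 with quantile normalization; adjusted p = 0.779), with the mitochondrially encoded gene mt-Nd2 higher and the nuclear gene Atp5b lower. Imprinted genes had 8 rises and 13 falls among 30 (9 and 14 adjusted over the list alone, 12 and 11 with TMM-like scaling; adjusted p = 0.874), with Grb10 going from 123.2 ± 1.41 to 40.3 ± 1.15 FPKM and Slc22a18 from 3.07 ± 0.17 to 12.9 ± 0.721 FPKM. FGF and ERK feedback targets had 8 rises and 11 falls among 22, also adjusted over the list alone (adjusted p = 0.75), and the AP-1 component gene Fosl1 rose from 4.08 ± 0.0141 to 22.0 ± 0.354 FPKM. With an estimated correlation, 0 of the 21 lists called at 48 h passed camera, and of all lists 1 had an unadjusted p under 0.05 (replication-dependent histones, 0.0255). Lists with an estimated correlation below the preset 0.01 lost their call here too (necroptosis and pyroptosis −0.006, interferon-stimulated genes −0.025). Other called lists had estimates far above it (ribosomal proteins 0.81, G2/M and mitosis 0.415, cholesterol synthesis 0.344). If these are right, the p-values of those lists at the preset correlation are too small. The version with an estimated correlation has little power and does not decide whether the calls hold.

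**Figure D2:**
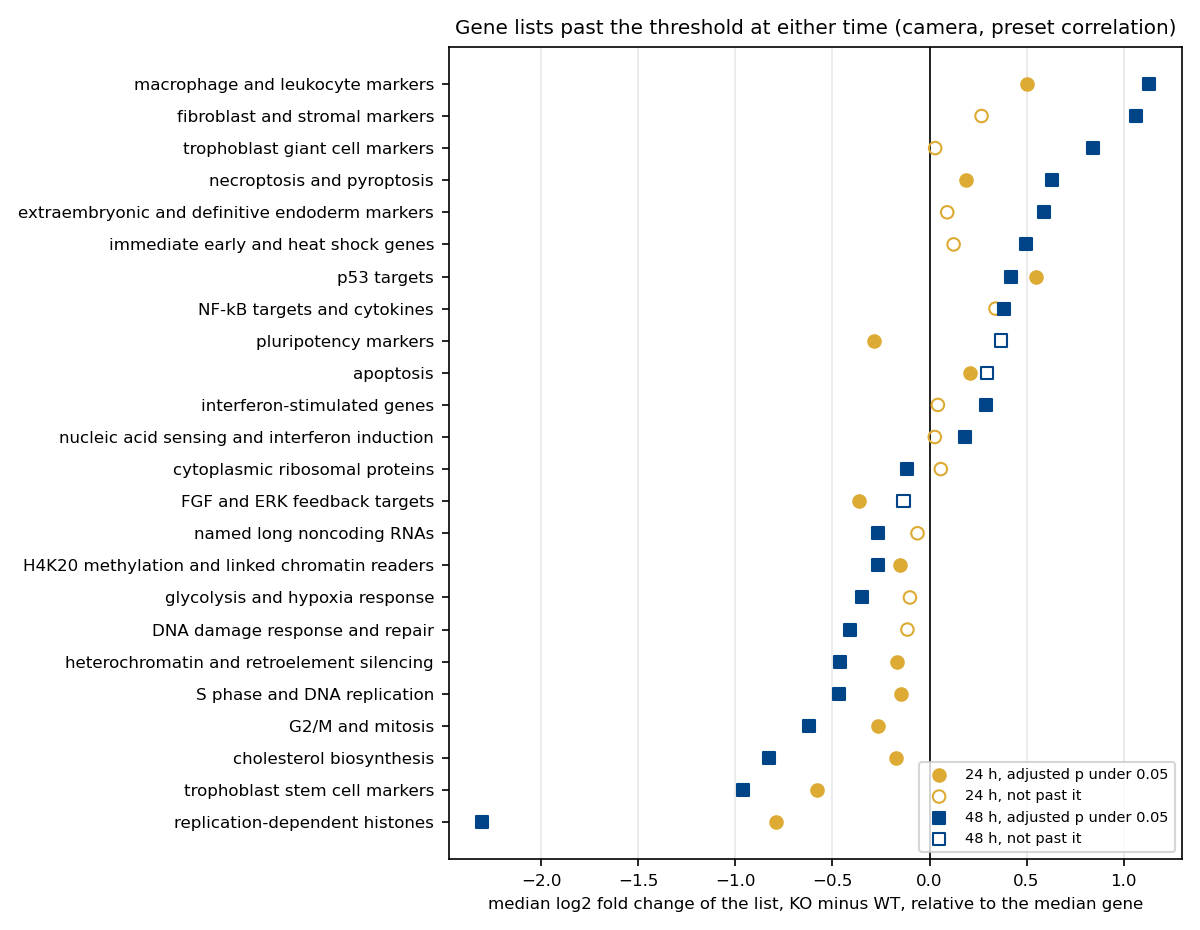
Median log2 fold change (KO minus WT, relative to the median gene, x axis) of each gene list that passed camera at either time (y axis), at 24 h (circles) and 48 h (squares), filled where the adjusted p at the preset correlation was under 0.05. Replication-dependent histones lie lowest at both times, at −0.79 and −2.31, and macrophage and leukocyte markers highest at 48 h, at 1.13. None of these calls held with an estimated correlation, a version of the test that has little power with so few libraries.

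The third comparison asked whether the change at 48 h differed from that at 24 h. Over 12519 genes tested at both times, the log2 changes had a Pearson r of 0.72 and a Spearman rho of 0.69 across genes, which are not independent replicates. Of 1726 genes that rose at 24 h and 2625 that rose at 48 h, 1293 did both, where independent lists would share 361.9. Of 1946 that fell at 24 h and 5037 that fell at 48 h, 1667 did both (783 for independent lists). Only 58 genes rose and then fell and 36 fell and then rose. The difference itself passed for 4666 of 12520 genes, 1294 more positive and 3372 more negative at 48 h, and the median gene was lower by −0.15. Time cannot be told apart from batch here, since each time has its own separately made table, nor from a difference in cells or library type, since the titles name the cells differently (PB-TSC at 24 h, mTSC at 48 h).

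The fall of Sox2 was larger at 48 h (unadjusted log2 change −3.44) than at 24 h (−1.26), an unadjusted difference of −2.18 (SE 0.174, adjusted p = 0.00056). Relative to the median difference of the genes in both tables, −0.15, it was −2.04, and the other differences of genes and lists are relative to that median. Cited1 (difference −1.96) and the histone genes H4c12 (−2.2), H2bc12 (−2.14) and H2bc11 (−1.74) had the other largest negative differences. In the other direction, Pla1a, encoding a phospholipase, had an unadjusted log2 change of 0.32 at 24 h and 2.85 at 48 h (difference 2.67, SE 0.1, adjusted p = 0.00027). Lrrc32 (difference 2.73), the annexin gene Anxa8 (2.69), the tubulin gene Tubb3 (2.48) and Fn1 (2.36) had the other largest positive differences. WT levels of some of these differed widely between the separately made tables, with Anxa8 at 21.7 ± 2.01 FPKM at 24 h and 2.49 ± 0.311 FPKM at 48 h, and Fn1 at 31.3 ± 9.67 and 2.94 ± 0.184 FPKM. The change of Kmt5a did not pass this test (unadjusted difference 0.00, SE 0.065, adjusted p = 0.999).

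Of 29 lists, 14 differed between the times at the preset correlation and 0 in camera with an estimated correlation (adjusted p between 0.388 and 0.936; 1 list at an unadjusted p under 0.05). The replication-dependent histones had the largest median difference in size, −1.48 (adjusted p = 2.86e-16; adjusted p = 0.388 with an estimated correlation), and cholesterol synthesis genes had the next most negative, −0.56 (adjusted p = 3.23e-08; adjusted p = 0.388 with an estimated correlation). S phase genes differed by −0.38 (adjusted p = 5.8e-09; adjusted p = 0.388 with an estimated correlation). Macrophage markers differed by 0.68 (adjusted p = 0.00646; adjusted p = 0.388 with an estimated correlation) and necroptosis genes by 0.6 (adjusted p = 0.000123; adjusted p = 0.388 with an estimated correlation). The p53 targets differed by −0.19 (adjusted p = 0.00717; adjusted p = 0.41 with an estimated correlation).

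**Figure D3:**
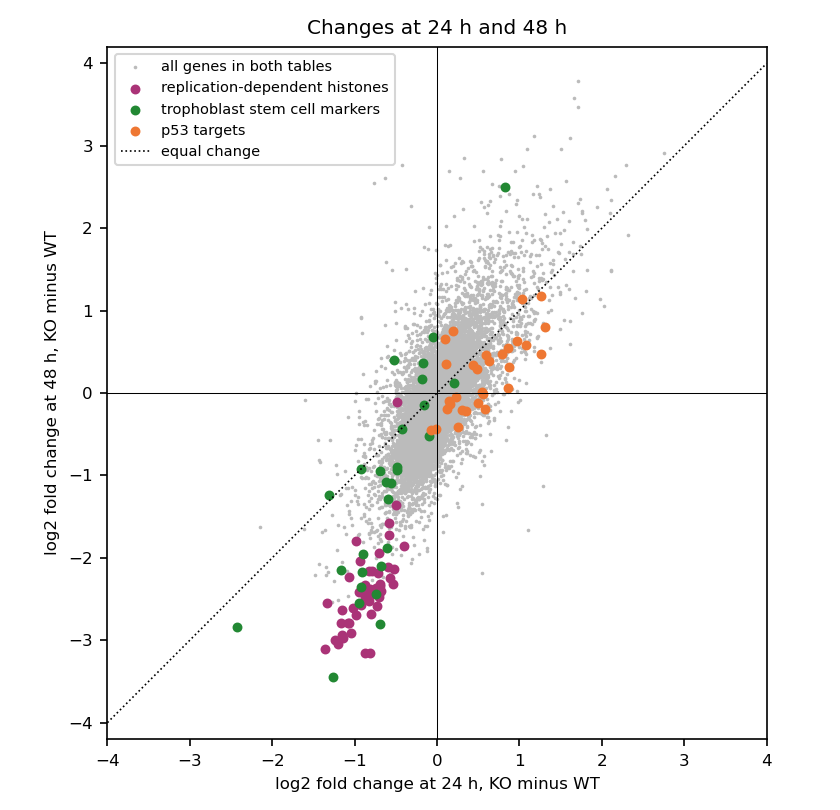
Unadjusted log2 fold change (KO minus WT) at 24 h (x axis) and 48 h (y axis) of each gene in both tables (grey), with replication-dependent histones, trophoblast stem cell markers and p53 targets coloured and a dotted line of equal change. The histone genes had medians of −0.79 and −2.31 relative to the median gene, and the changes of all genes correlated with a Pearson r of 0.72.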

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

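The tests of explanations in this part were all chosen after the results were seen, whereas the tests of the difference between 24 h and 48 h were planned. The change between KO and WT cells differed between the times for 4666 genes and for 156 of the 209 named genes tested at both times, 53 more positive and 103 more negative at 48 h. These genes, and the genes and lists whose differences are given next, stood out because the test of that difference passed, and since each time has its own table, time cannot be told apart from batch, cells or library type for any of them. Values are log2 differences relative to the median difference, −0.15. The largest positive ones were 2.73 for Lrrc32, 2.69 for Anxa8, 2.67 for Pla1a, 2.48 for Tubb3 and 2.36 for Fn1. The largest negative ones were −2.2 for H4c12, −2.14 for H2bc12, −2.04 for Sox2, −1.96 for Cited1 and −1.74 for H2bc11. Median differences of lists were more negative at 48 h for replication-dependent histones (−1.48), cholesterol synthesis (−0.56), S phase (−0.38), trophoblast stem cell markers (−0.29), G2/M and mitosis (−0.28), DNA repair (−0.26), p53 targets (−0.19), heterochromatin and retroelement silencing (−0.15) and ribosomal proteins (−0.12). They were more positive for macrophage markers (0.68), necroptosis and pyroptosis (0.60), fibroblast markers (0.54), immediate early and heat shock genes (0.31) and nucleic acid sensing (0.19). With an estimated correlation, adjusted p was at least 0.388 for every one of these lists.

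Replication-dependent histone transcripts fell further at 48 h than other replication genes, with a median log2 change of −2.31 against −0.47 for the S phase list. These transcripts lack a poly(A) tail, and lower recovery of such RNA in KO libraries could not be settled. Small RNAs without a tail had a median change of −0.12 over 597 genes. They can be recovered differently from longer transcripts, and some lie within other genes, so this median does not decide it. A different division of reads among near-identical copies is argued against by the summed FPKM of the 49 genes, whose log2 ratio was −2.48. Fewer KO cells in S phase stays open. Of the S phase list 87.2% fell, beside 36.3% of all tested genes, but 38 of 40 genes of the G2/M list fell as well, and a share of genes that fell does not account for the larger fall of histone transcripts.

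More genes were lower than higher at 48 h, at 61.4% of the calls. A different scale of the deposited values in the groups cannot be told apart from a true excess of falls. With every library scaled to the same FPKM sum 49.5% of the calls were lower, but this also moved the median gene from −0.12 to −0.02, and the share follows where the median gene is put. A larger share taken by the most abundant entries in KO libraries is argued against, because the lower KO share of the top 10 entries, 31.1%, lay within the WT range of 28.2% to 33.7%. No biological explanation was tested, and without spiked-in RNA the total RNA per cell is unknown.

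Kmt5a transcripts were at 82.2% of WT at 48 h, where 8719 genes were called. A library with the wrong group label is argued against, because the lowest correlation within a group at 48 h was 0.988 and the highest between groups 0.914. An effect of doxycycline cannot be told apart from loss of the gene, because no library had doxycycline without the deletion. Targets of the stress factor ATF4 had a median change of −0.002 at 24 h, which does not settle it. Cells that kept an intact gene cannot be told apart from cells that make a transcript lacking only part of it, since the KO level of 82.2% of WT is a value for the whole gene.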

How the results depend on the processing

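Scaling to equal FPKM sums was chosen after seeing the data, and the other alternatives were planned. No result was called in the opposite direction, but the median of ribosomal protein genes at 48 h turned from −0.12 to 0.017 with quantile normalization (adjusted p = 0.499), for a cause not tested. The number of calls at 24 h was 1224 to 2170 with 1 library left out (3725 with all), and 259 with a log2 change of at least 1. At 48 h it was 5759 with a mean FPKM of at least 5 and 1465 with a log2 change of at least 1 (8719 without these), the former with fewer genes tested. The number that differed between times was 390 with a difference of at least 1 (4666 without). With an estimated correlation 0 lists were called at 24 h and 0 at 48 h, and with a mean FPKM of at least 5 there were 12 at 48 h (21 without). The unadjusted log2 change of Kmt5a was −0.30 to −0.25 at 24 h with 1 library left out and −0.32 to −0.23 at 48 h, and the cause was not tested. At 48 h it was −0.13 with TMM-like scaling and −0.15 with equal FPKM sums (−0.28 without), scalings that also moved the median gene from −0.12 to −0.002 and −0.022. The correlation of changes between times was 0.688 with a pseudocount of 0.1, 0.765 with a mean FPKM of at least 5 and 0.665 to 0.725 with 1 library left out. Among single named genes, 3171 values under alternatives kept their side of the threshold, 139 lost their call and 17 gained one. Among lists, 458 kept it, 1 turned and 59 lost it, 34 of them with an estimated correlation. Dropping the minimum mean FPKM tested little, because low genes had been left out before deposit. A test on counts was not run, because FPKM gives no whole reads. Depth is unknown and limits low genes most.

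With the replicate number as a block at 24 h, 4851 genes and 14 lists were called and Kmt5a was at −0.28 (adjusted p = 0.0137). The numbers are not known to pair the libraries, and the deviations of the libraries numbered 1 had a correlation of 0.193 across genes. No paired analysis was run at 48 h, because the titles of the groups share no replicate number and the column numbers of the KO libraries match no title.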

Other observations

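The gene lists in this part were chosen after seeing the data, and their tests serve as description. Genes of stratified epithelium and the cornified envelope rose together at 48 h, 21 of 24 measured, with 3 falling and a median log2 change of 1.77 (camera adjusted p = 8.62e-10; adjusted p = 0.181 with an estimated correlation). The list holds 50 genes, of which 24 were measured at 48 h and 18 at 24 h. Genes low in WT would be measured only if higher in KO, which favours rises in this list. Besides Evpl, the desmosome gene Pkp3 rose from 14.5 ± 0.29 to 61.5 ± 1.2 FPKM (mean ± SD, n = 2), the integrin gene Itgb4 from 3.36 ± 0.368 to 24.4 ± 0.863 FPKM, the laminin gene Lamc2 from 3.19 ± 0.0707 to 20.1 ± 0.304 FPKM and the keratin gene Krt15 from 2.49 ± 0.248 to 22.0 ± 2.33 FPKM. At 24 h 8 of 18 rose and 1 fell (median 0.29, adjusted p = 3.01e-05; adjusted p = 0.336 with an estimated correlation). Genes of lysosomal proteins rose as well, 24 of 29 at 48 h with 2 falling (median 0.69, adjusted p = 6.59e-09; adjusted p = 0.181 with an estimated correlation). Man2b1 went from 19.9 ± 0.693 to 87.4 ± 1.54 FPKM, Tpp1 from 15.5 ± 0.00707 to 51.8 ± 0.714 FPKM and the protease gene Ctsd from 119.0 ± 2.21 to 247.6 ± 6.92 FPKM. This list includes Cd68, which the macrophage list also holds. At 24 h 12 of 29 rose and 1 fell (median 0.18, adjusted p = 3.01e-05; adjusted p = 0.384 with an estimated correlation).

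Of 10 mitochondrially encoded genes at 48 h, 7 rose and 0 fell (median 0.81, adjusted p = 0.00144; adjusted p = 0.219 with an estimated correlation), mt-Cytb from 278.3 ± 24.5 to 493.0 ± 33.5 FPKM, while in limma 0 of 9 passed at 24 h (2 at an unadjusted p under 0.05; median 0.05). Of 16 mitochondrial transfer RNA entries, 10 rose at 48 h. Linker histone genes fell at 48 h in all 5 cases (median −2.29, adjusted p = 0.000957; adjusted p = 0.181 with an estimated correlation). All 5 are also on the list of replication-dependent histones, so their fall is part of that result and not separate evidence. Of 10 replication-independent histone variant genes, whose transcripts carry poly(A) tails, 9 fell and 1 rose (median −0.55, adjusted p = 0.00686; adjusted p = 0.181 with an estimated correlation), with H1f10 going from 84.4 ± 11.4 to 17.4 ± 0.248 FPKM. Genes for histone mRNA transcription and processing had 9 falls and 1 rise among 14 (median −0.35, adjusted p = 0.0397; adjusted p = 0.526 with an estimated correlation). Targets of ATF4 had 4 rises and 8 falls among 17 at 48 h (adjusted p = 0.407). Of 7 globin genes Hba-a1 alone was measured, and its log2 change was 1.74 at 24 h and 3.91 at 48 h.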
